A study of Mus musculus with 3 samples.

How the data were processed

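Total RNA sequencing had been run on the chromatin fraction of bone-marrow-derived macrophages in 3 libraries of 1 condition, per the labels. Fragments of 250 to 400 were selected, a size range that the labels give without a unit. The authors deposited a gene table for each library with expected counts and TPM, made from a transcriptome alignment to mm10 with GENCODE M21 annotation, per the file headers and accompanying notes. They also deposited transcript tables of expected counts and TPM in the same format, and a second set of transcript tables of estimated counts and TPM made straight from the reads. The columns of the first kind are those that RSEM writes and the columns of the second kind those that kallisto writes. The aligner, the quantifiers and their versions are not given in the sources used here, nor is the treatment of strand, so reads of a gene and an overlapping antisense gene may be mixed. TPM has a fixed sum over everything a table holds, so abundant short RNAs lower the TPM of all other genes.

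Gene symbols, classes and coordinates came from the GENCODE M21 annotation, which held all 55536 gene identifiers of the tables. The second set was summed per gene, and 86 identifiers absent from it were set to 0. A symbol with several identifiers was represented by the one with the highest mean expected count, which affected Rmrp, Mirt2 and Aldoa. The list members Faim3, Ahsp, Rn7sl1 and Norad were not found under these symbols. Entries for tRNA, spike-in and phiX sequences were kept out of library sizes and tests. They held 1.39%, 0.288% and 0.283% of expected counts in replicates 1, 2 and 3. Library totals on genes ranged from 13538605 to 19949204. The limits quoted for genes with no counts, at 3 counts, cover counting error only, since reads without molecular identifiers are not independent molecules.

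The analyses followed a plan fixed before the data were examined, apart from the additions named at the end of this section. Samples formed 1 group, so no test between conditions was made, and p-values measure only the spread between these 3 libraries. RNA input differed between replicates with 1 library at each amount, so no effect of input was tested. A gene was called detected at a TPM of 1 or more in all 3 libraries and not detected below 0.1 in all of them. The level of a list in a library was the median of log2(TPM + 0.1) over its members. It was placed among 10000 random lists of equal size, drawn from protein-coding genes or, for noncoding RNAs, from noncoding genes. The 6 differences between lists were taken within each library and tested by an exact two-sided sign-flip test.

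Expected counts were rounded to whole numbers for count models. In edgeR 4.0.16 (R 4.3.3), genes were kept by filterByExpr, libraries scaled by TMM, and an intercept-only model fitted with a trended negative binomial dispersion. Each gene's deviance was compared with a chi-square distribution and adjusted by the Benjamini-Hochberg method. The spread of a list was the median SD of log2 CPM (prior count of 2), placed among 10000 random lists matched in 10 bins of mean level. Further work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

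The goodness-of-fit step was tested on simulated counts with the real means, library sizes and trended dispersions. In these counts 200 genes were changed in 1 library. Unchanged genes followed the trend exactly, so the simulation does not cover false calls from real genes that scatter around it. At a 4-fold change 174 of 198 tested genes were recovered (87.9%), and at a 2-fold change 19 of 196 (9.69%), each with 1 false call. Changes near 2-fold in a single library are therefore mostly missed. In simulated lists of 30 genes, 12 of 200 lists with unshifted level (6.00%) and 200 of 200 lists with level shifted by 1 SD passed the 95th percentile. These rates are for the level of a list, so they do not give the error rate of calls on its spread.

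The text names the 10 protein-coding and 8 noncoding genes of highest mean TPM, up to 4 highest members and the lowest member of a list, a set of response genes chosen in advance, and the 10 genes of smallest p in the goodness-of-fit test with a mean TPM of at least 1. The value of 1 gene among these is not reported here. The 32 lists covered parts of the Lipid A and interferon responses, activation states, macrophages, 12 other cell types, noncoding RNA, ribosomal protein, mitochondrial, histone, cell cycle, glycolysis, lysosome, NADPH oxidase, MHC class II, cholesterol and sex-linked genes. Alternatives covered DESeq2 1.42.0 size factors and dispersion outliers, no filter on low counts, the read-based tables, other thresholds and pseudocounts, counts without length scaling, means over members, rescaled TPM, expected counts for shares, and leaving out each replicate. Fits on protein-coding nuclear genes only, and the tests of technical explanations other than that of GC content and length, were added after seeing the data.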

Results

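RNA bound to chromatin was sequenced from mouse bone-marrow-derived macrophages, primary cells grown from marrow precursors, of the C57BL/6J strain. Lipid A is the part of bacterial lipopolysaccharide that the receptor TLR4 recognises. The cells received 100 ng/ml Lipid A for 12 h, spent 12 h without it, and were then exposed again at 100 ng/ml for 10 min. Ribosomal RNA was depleted before sequencing, and the chromatin fraction holds RNA that is being made or has not left its gene. All 3 libraries belonged to this 1 condition. The labels call them biological replicates, with separate biosamples and a shared donor identifier. No untreated or singly stimulated library was analysed here, so each comparison lies between gene groups within a library or between replicates. Expected counts on genes, rounded per gene, summed to 13538605, 19949204 and 18224466 in replicates 1, 2 and 3. By counting error alone, a gene with no counts could make up 0.222, 0.150 or 0.165 CPM (counts scaled to library size) in these libraries, the limit that 3 counts set. It is no limit where a 0 is a failed estimate. The labelled RNA input was 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3.

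By mean abundance the highest protein-coding RNA on chromatin was that of the interferon-induced gene Mx1 (ENSMUSG00000000386.15, mm10 chromosome 16, 97447035 to 97462907). It stood at 1977 ± 869 TPM (the deposited length-scaled abundance, with SD, n = 3). Rsrp1 followed at 1406 ± 189, then the class I histocompatibility gene H2-K1 at 1386 ± 138 and Tcirg1, a subunit of the vacuolar proton pump, at 1270 ± 284. Mx1 was not highest by every measure: in replicate 3 it was at 1253 TPM against 1328 for Tcirg1, and by mean expected counts it was at 42929 against 49643 for Rsrp1. The inhibitory receptor gene Lilrb4a reached 1220 ± 129, the adaptor gene Fyb 1035 ± 170 and Ikbke, a kinase that acts on interferon regulatory factors, 1005 ± 145. Zeb2, Hnrnpa2b1 and Gpnmb stood at 967 ± 165, 963 ± 40.9 and 924 ± 94.6 TPM. In all, 13530 genes had a TPM of at least 1 in every library, of which 10050 were protein-coding out of 22028 annotated, and 1408 were long noncoding. A further 33662 gene identifiers were below 0.1 TPM in all 3 libraries. The gene count depended on the quantification: 20888 genes passed in the read-based transcript tables, and 8476 at a threshold of 5 TPM.

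Noncoding RNA took most of the TPM. Small noncoding genes held 55.6% ± 3.25 and protein-coding genes 29.4% ± 1.85 (SD, n = 3). By expected counts the order was the other way, at 1.84% ± 0.352 and 63.3% ± 5.27, and in the read-based TPM they were at 37.2% ± 2.11 and 40.1% ± 4.72. The 10 highest genes took 37.8% ± 3.02 of TPM. Among noncoding genes, Rmrp, the RNA of the mitochondrial RNA processing ribonuclease, was at 75350 ± 37681 TPM by the gene tables and 30207 in the read-based tables. A second annotated copy of Rmrp shares reads with it, so the split between them is uncertain. Gm26917 lies within a ribosomal RNA repeat on chromosome 17 (39843013 to 39846341) and reached 57361 ± 23639 TPM, or 66272 in the read-based tables. That repeat, with Gm42418 and CT010467.1, took 9.97%, 21.3% and 23.5% of expected counts in replicates 1, 2 and 3. Malat1, a nuclear speckle RNA (chromosome 19, 5795690 to 5802672), stood at 28992 ± 8643 TPM and Neat1, the scaffold of paraspeckles, at 2317 ± 439. The snoRNA genes Gm22988, Gm26447 and Snord15b showed 75276 ± 32656, 40426 ± 15696 and 30104 ± 9247 TPM, but only 8500, 2063 and 3706 in the read-based tables. Snord22 was at 12407, 0 and 42693 TPM in replicates 1, 2 and 3, although replicate 2 held 756 expected counts, so TPM of RNAs this short is unsteady.

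The first comparison asked which parts of the Lipid A response were on chromatin 10 min into the second exposure. Interferon-stimulated genes stood highest: all 30 of 30 members were detected, with a median of 6.94 ± 0.27 on the log2(TPM + 0.1) scale (SD, n = 3). After Mx1, the leading members were Stat2, a transducer of interferon signals, at 671 ± 122 TPM, the antiviral gene Rsad2 at 566 ± 240 and Oasl2 at 527 ± 74.8. The lowest member, Isg20, still reached 13.9 ± 5.54 TPM. Proinflammatory cytokines and chemokines had a median of 1.13 ± 0.31, or 1.96 in the read-based tables, with 15 of 30 members detected. The difference between both lists was 5.81 ± 0.10 on the log2 scale, 56.1-fold, and had the same sign in 3 of 3 libraries. It was 23.7-fold with members under a mean of 0.1 TPM left out.

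Within the cytokine list, chemokines led. Ccl5 stood at 163 ± 90.3 TPM, Cxcl10 at 89.5 ± 64.3, Ccl4 at 52.5 ± 11.6 and Ccl3 at 32.7 ± 10.1. Tnf, the early macrophage cytokine (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), reached 45.2 ± 12.1. Il1b and Cxcl2 were lower, at 7.12 ± 3.67 and 5.50 ± 0.773. The interferon gene Ifnb1 was at 0.907 ± 0.667 TPM and Il6 at 0.300 ± 0.270, on 9, 6 and 4 expected counts. Il12b, a subunit of interleukin 12, had 1, 3 and 1 counts and 0.0633 ± 0.0404 TPM. Cxcl3 was listed at 0 in all libraries, while the read-based tables gave it 0.318 TPM.

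Genes of NF-κB feedback and tolerance, a list that also holds the NF-κB subunit genes Rel, Relb, Nfkb1 and Nfkb2, were detected for 28 of 30 members. Their median was 4.24 ± 0.23. They lay above the cytokine list by 3.11 ± 0.12 on the log2 scale, 8.66-fold, in 3 of 3 libraries, and by 3.65-fold with members under a mean of 0.1 TPM left out. By mean TPM Cd274, which encodes the checkpoint ligand PD-L1, was highest at 195 ± 43.8. The inositol phosphatase gene Inpp5d, at 184 ± 20.3, lay within that spread, so their order is not settled. The phosphatase gene Ptpn6 was at 112 ± 25.1 and Tnip3 at 102 ± 35.8. Nfkbia, which encodes the inhibitor IκBα, reached 56.2 ± 15.6 and Tnfaip3, the deubiquitinase A20, 45.3 ± 10.3. Irak3, an inhibitor of TLR signalling, was at 19.9 ± 5.36, Il10 at 8.33 ± 4.92 and Socs3 at 6.44 ± 2.86 TPM. Cish was lowest at 0.393 ± 0.163. Genes of the TLR4 pathway itself had a median of 4.39 ± 0.03 and 29 of 30 detected members, led by Ikbke, Tbk1 at 161 ± 31.8 and Map3k8 at 100.4 ± 23.2, with Chuk at 91.9 ± 7.18. Tlr4 stood at 23.2 ± 1.16 and Lbp, a serum protein gene, at 1.21 ± 0.883.

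Immediate early genes had 22 of 30 members detected and a median of 2.60 ± 0.53. Klf6 reached 84.8 ± 14.3 TPM, Plk2 57.1 ± 7.97, Zfp36, which encodes an mRNA-destabilising protein, 52.5 ± 10.8 and Junb 42.4 ± 14.2. Dusp1, a phosphatase of MAP kinases, was at 22.8 ± 6.22 and Fos at 16.8 ± 9.20. Egr1 stood at 1.67 ± 1.55 and Fosl1 at 0. The late Lipid A list had 16 of 30 members detected and a median of 1.41 ± 0.43, or 2.30 in the read-based tables. Apart from Mx1, which is also in the interferon list, its leading genes were Acod1, the enzyme that makes itaconate, at 167 ± 85.2 TPM, the acute-phase gene Saa3 at 135 ± 76.6 and Cp, which encodes ceruloplasmin, at 130 ± 57.9. Nos2, the inducible nitric oxide synthase, was at 3.83 ± 1.92 and Lcn2 at 0.657 ± 0.535. Immediate early genes lay above the late list by 1.19 ± 0.71, but the gap was 0.37 in replicate 1 against 1.64 and 1.55 in replicates 2 and 3. It narrowed to 0.48 ± 0.94 in the read-based tables, to 0.43 ± 0.71 in CPM without length scaling and to 0.35 ± 0.58 for means in place of medians. In each of these the SD exceeded the mean, so the direction was not stable.

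Markers of classical (M1) activation were higher than markers of alternative (M2) activation by 3.56 ± 0.50 on the log2 scale, 11.8-fold, in 3 of 3 libraries. The fold was 3.84 for means over members, 4.71 in the read-based tables, 5.06 with a pseudocount of 1, 6.13 in CPM without length scaling and 6.64 with members under a mean of 0.1 TPM left out. In the M1 list 13 of 18 members were detected, at a median of 2.69 ± 0.79. Acod1, Cxcl10 and Tnf led it with Irf5, at 44.1 ± 5.82 TPM, or 136 in the read-based tables. These 3 leading genes also belong to the Lipid A lists above. In the M2 list 6 of 18 members were detected, at a median of −0.87 ± 0.42, or 0.70 in the read-based tables. Its highest members were not low: Stab1, a scavenger receptor gene, stood at 450 ± 141 TPM, Il4ra, the interleukin 4 receptor, at 66.2 ± 22.7, the mannose receptor gene Mrc1 at 38.5 ± 8.39 and Cd200r1 at 38.4 ± 2.88. Ccl24 was listed at 0, against 6.48 TPM in the read-based tables.

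For each of the 6 differences between lists, the 4 above and those of macrophage and noncoding genes, the exact two-sided sign-flip test over 3 libraries gave p = 0.25, the smallest it can give. No multiple-test adjustment can lower it, so each difference is a value with its spread. Against 10000 random lists of protein-coding genes, the medians of the interferon, NF-κB feedback and TLR4 lists were at the 100th percentile. The ribosomal protein, lysosomal, mitochondrial and cholesterol lists were there too. The random lists drew on all 22028 protein-coding genes, of which 8420 were below 0.1 TPM in every library. A high percentile therefore does not by itself mark a response to Lipid A or interferon. The immediate early list was at 97.6, M1 at 95.4, the late list at 84.6, cytokines at 80.6 and M2 at 46.1.

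**Figure D1:**
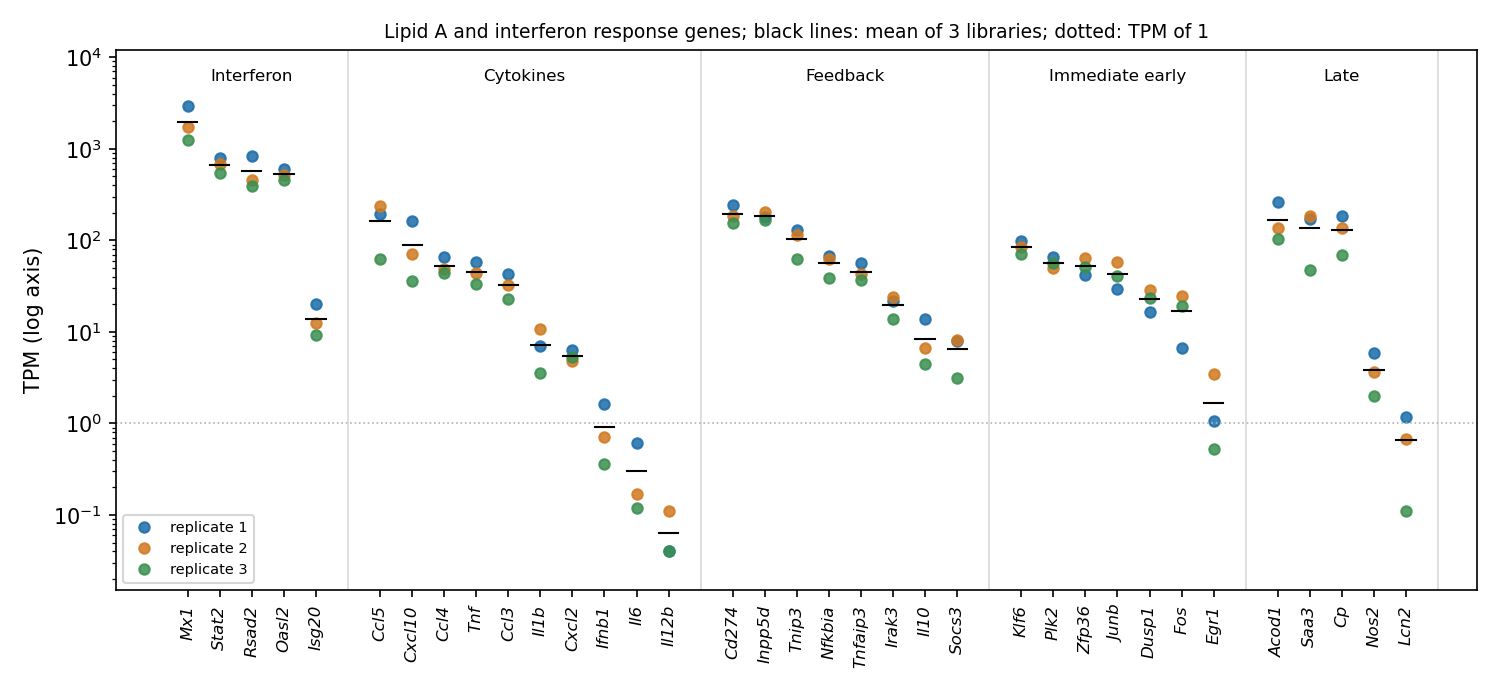
TPM of Lipid A and interferon response genes on a log axis, grouped by list, with a point for each of the 3 replicates, a black line at their mean and a dotted line at 1 TPM. Mx1 lies highest at a mean of 1977, Tnf at 45.2 and Il6 below the dotted line at 0.300.

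The next comparison asked whether the chromatin RNA carried the marks of macrophages or of other cells. Macrophage genes were detected for 29 of 30 members, with a median of 6.29 ± 0.28. Gpnmb was followed by Sirpa, an inhibitory receptor gene, at 733 ± 50.3 TPM, the cathepsin gene Ctsb at 425 ± 15.6 and Adgre1, which encodes F4/80, at 303 ± 76.5. Csf1r, the receptor for the macrophage growth factor, stood at 139 ± 11.5. Cx3cr1 was the exception at 0, 3 and 0 expected counts, against 3.22 TPM in the read-based tables. Pooled markers of T, B, NK, mast, erythroid, fibroblast, endothelial and epithelial cells had a median of −3.23 ± 0.15, and 18 of 130 were detected. The difference was 9.52 ± 0.19 on the log2 scale, in 3 of 3 libraries, and 6.30 with a pseudocount of 1.

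Few genes of other lineages stood out. The neutrophil list had 1 of 18 members detected, Csf3r, the receptor for granulocyte colony-stimulating factor, at 98.3 ± 21.2 TPM. Ngp was at 0.477 ± 0.0321 and Stfa1 at 0. Among T cell genes Cd28 stood at 17.4 ± 2.56 and Cd4 at 7.81 ± 1.24, and Ctla4 was listed at 0. B cell genes were led by Cd72 at 108 ± 56.8, which lay at 173 TPM in replicate 1 against 86.0 and 66.3 in replicates 2 and 3, and by Cd22 at 11.2, 4.56 and 2.36 in replicates 1, 2 and 3. Dendritic cell genes had 4 of 16 members detected, with Tcf4 at 112 ± 20.4 and Batf3 at 8.19 ± 3.16. No member of the NK list (14 genes) or the epithelial list (14 genes) was detected. These counts hold for the gene tables. Klrk1, the highest NK gene there, was at 1.15 ± 1.09, while the read-based tables gave 1.37 TPM for Klrk1 and 3.28 for Klre1. Cldn7, the highest epithelial gene, was at 0.340 ± 0.473. Tfrc, the transferrin receptor, led the erythroid list at 63.4 ± 17.2 and Vwf the endothelial list at 28.2 ± 7.50.

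**Figure D2:**
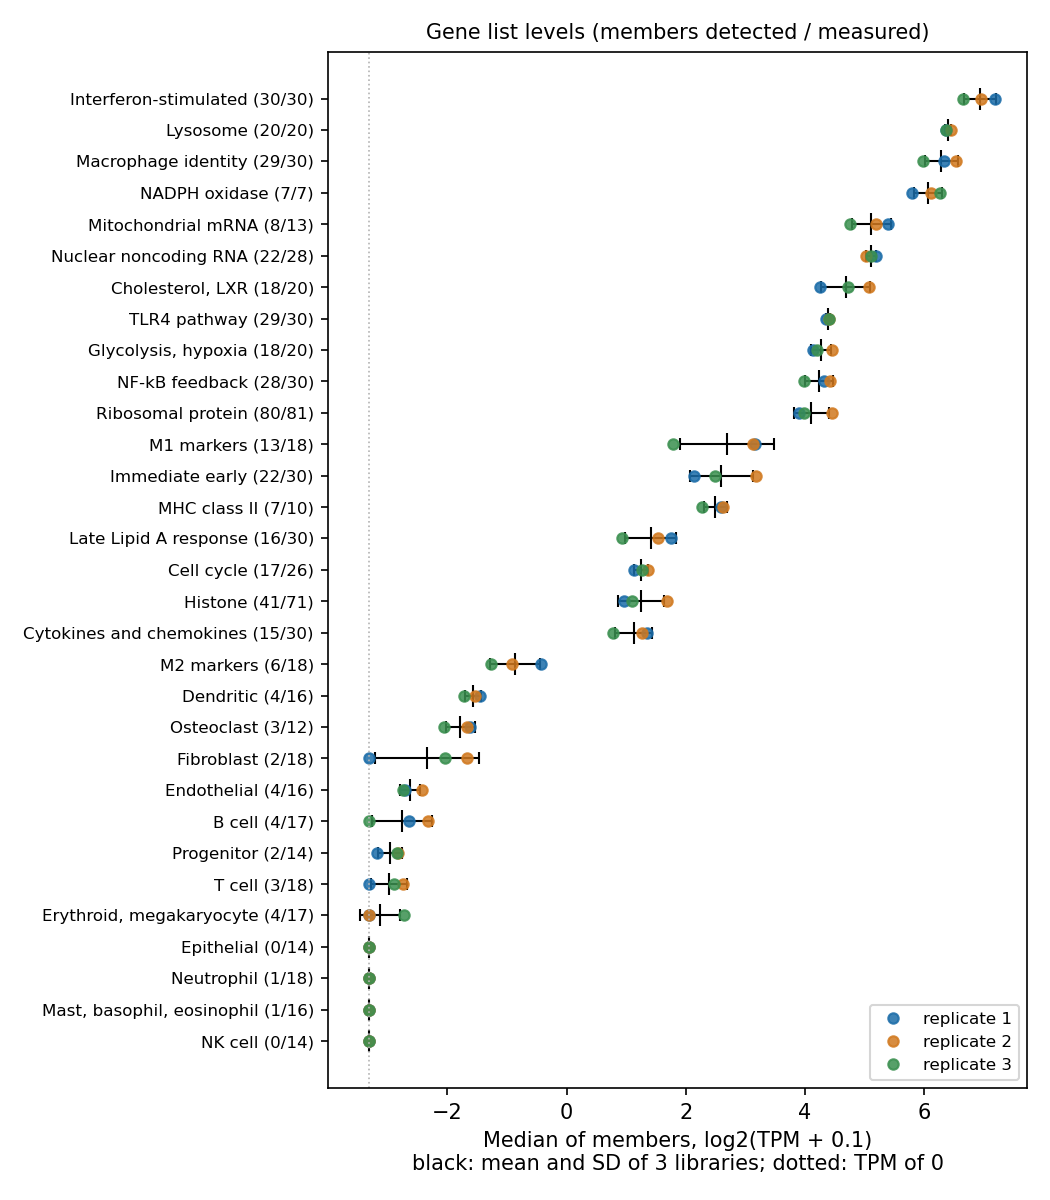
Median log2(TPM + 0.1) of each gene list, with a point per replicate, the mean and SD of the 3 libraries in black, and detected over measured members in the labels. Interferon-stimulated genes lie highest at 6.94 and the NK list at the value of 0 TPM.

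A further comparison set nuclear noncoding RNAs against ribosomal protein genes, whose mature mRNAs are abundant in cytoplasm. No cytoplasmic or whole-cell library was analysed here, so this comparison cannot show enrichment in the chromatin fraction. The noncoding list had 22 of 28 measured members detected and a median of 5.11 ± 0.08. Besides Rmrp, Gm26917 and Malat1 it was led by the transcription regulator Rn7sk at 17816 ± 2096 TPM. Meg3 was listed at 0. Ribosomal protein genes were detected for 80 of 81 members at a median of 4.11 ± 0.30, with Rpl10 at 117 ± 12.3 TPM, Rps9 at 101.3 ± 28.5 and Rpl3 at 97.8 ± 20.6. The noncoding list lay above them by 1.00 ± 0.38 on the log2 scale in 3 of 3 libraries, and by 2.36 without length scaling.

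Transcripts annotated as retaining an intron took 37.1% ± 0.559 of the TPM of protein-coding genes, and transcripts annotated as coding took 49.7% ± 0.769. By expected counts the retained-intron share was 23.7% ± 0.769. For gene groups the share was taken of TPM summed over members, so abundant members such as Ikbke and Mx1 weigh most. The number of annotated retained-intron transcripts in a group was not taken into account. By TPM the share differed between gene groups: 53.6% ± 1.05 in TLR4 pathway genes, 51.3% ± 1.07 in ribosomal protein genes, 33.0% ± 0.920 in interferon-stimulated genes and 18.4% ± 0.993 in immediate early genes. It was 25.7% ± 5.17 in cytokine genes. In the read-based tables TLR4 pathway genes were at 55.0%, ribosomal protein genes at 45.4% and interferon-stimulated genes at 34.1%. There immediate early genes, at 23.8% ± 3.43, were no longer below cytokine genes, at 22.0% ± 4.26. Histone and mitochondrial genes have no such annotated transcripts and were at 0. Reads of unspliced RNA can be assigned to such transcripts, so the share does not measure an event at 1 intron.

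Mitochondrial genes held 0.0817% ± 0.0240 of TPM. In the list of 13 mitochondrial mRNAs, 8 were detected in every library, led by mt-Co1 at 263 ± 97.9 TPM, mt-Atp8 at 214 ± 73.9 (79.3 in the read-based tables) and mt-Nd6 at 73.7 ± 21.5. For mt-Co2 the gene tables gave 0 TPM in all libraries and the read-based tables a mean of 32.0, so a 0 in the gene tables can be a failed estimate.

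Replicates were compared with one another last, since their spread is the error of every level above. Across 24595 genes with any count, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.943 for replicates 1 and 2, 0.944 for 1 and 3 and 0.952 for 2 and 3. Spearman's rho was 0.934, 0.933 and 0.943. The common biological coefficient of variation was 0.167 over 14789 genes, and 0.111 when replicate 1 was left out. By edgeR's goodness-of-fit test, 167 genes varied more between libraries than genes of their level at a Benjamini-Hochberg adjusted p below 0.05. Of these, 93 were protein-coding and 31 small noncoding, and 131 were highest in replicate 1. Without replicate 1, 2 or 3 the count was 57, 68 or 52, in fits that also had fewer libraries, and DESeq2 called 61 dispersion outliers.

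Several named response genes were among them. Cxcl10, a chemokine induced by interferon (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), stood at 161, 71.9 and 35.8 TPM in replicates 1, 2 and 3 (edgeR adjusted p = 1.42e-12). Saa3 was at 173, 186 and 47.2 (adjusted p = 1.11e-06) and Ccl5 at 192, 236 and 62.1 (adjusted p = 4.19e-05). Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) was lowest in replicate 1, at 6.67, 24.7 and 19.0 TPM (adjusted p = 0.000173). Egr1 was at 1.07, 3.43 and 0.520 (adjusted p = 0.000286), Nos2 at 5.83, 3.66 and 2.00 (adjusted p = 0.00154), Acod1 at 264, 136 and 103 (adjusted p = 0.00884) and Il10 at 13.9, 6.60 and 4.51 (adjusted p = 0.00888). The 10 genes of smallest p were copies of a single RNA family, U1 snRNA, the spliceosomal RNA that pairs with the 5′ splice site. Among them Gm22513 (chromosome 12, 54696782 to 54696945) stood at 39624, 8262 and 9930 TPM, and Rnu1a1 at 10291, 2394 and 2999, with read-based means of 4407 and 1052. The others were Gm22614, Gm25890, Gm26444, Gm23804, Gm22068, Gm22317, Gm22634 and Gm25679. These copies share reads, so which copy varied is uncertain.

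As groups, 13 of 22 lists with at least 5 tested members varied more between replicates than 95% of random lists of the same level. Of these, 5 also did so without any 1 replicate, namely the late Lipid A, M1, cytokine, interferon and mitochondrial lists. The M1 list shares Tnf, Il1b, Il6, Il12b, Cxcl9 and Cxcl10 with the cytokine list. With the late list it shares Nos2, Acod1, Il6, Il12b, Fpr2 and Cd38. The late list also shares Il6 and Il12b with the cytokine list and Mx1 with the interferon list. Cxcl10, Nos2 and Acod1 were among the genes that passed. Some passing genes therefore count in several lists, and the calls of these lists are not independent. The late Lipid A list had the widest spread, a median SD of 0.76 on the log2 scale against 0.18 in random lists, and 7 of its 20 tested genes passed over all genes, or 18 adjusted over the list alone. Its spread was 0.34 without replicate 1, below that of histone and cytokine genes, and 0.45 without replicate 3. M1 markers followed at 0.63, with 5 of 14 genes passing, or 8 adjusted over the list alone, and their spread was 0.18 without replicate 1 and 0.29 without replicate 3. Cytokines stood at 0.50 with 3 of 18, or 6 adjusted over the list alone. Interferon-stimulated genes had a median SD of 0.41 against 0.14, with 1 of 30 passing, or 5 adjusted over the list alone, and 0.13 against 0.08 without replicate 1. Histone and mitochondrial genes were at 0.46 and 0.45, with 0 genes passing over all genes and 5 of 34 and 4 of 8 adjusted over the list alone. At an unadjusted edgeR p below 0.05, 7 histone and 5 mitochondrial genes passed, and DESeq2 called 0 of either as dispersion outliers. Without replicate 2 the histone spread was 0.23, at the 53.4th percentile. The calls of the other 7 lists were each lost as well without some replicate: immediate early at the 89.4th percentile, NF-κB feedback at 93.9 and B cell at 74.1 without replicate 1. They were also lost for glycolysis at 22.7, M2 at 57.3 and B cell at 92.3 without replicate 2, and for macrophage at 89.2, cholesterol at 86.6 and NF-κB feedback at 42.2 without replicate 3. TLR4 pathway, ribosomal protein and lysosomal genes did not exceed random lists, at the 51.0th, 37.7th and 11.2th percentiles, but ribosomal protein genes did without replicate 1, at 96.4.

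Some of the response lists shared a direction between replicates 1 and 3, and others did not. All 30 interferon-stimulated genes were higher in replicate 1 than in replicate 3, by a median of 0.80 on the log2 scale. So were 20 of 20 late Lipid A genes, by 1.37, 15 of 18 cytokine genes, by 1.00, and 8 of 8 mitochondrial mRNAs, by 0.89. Immediate early genes were split, with 14 of 26 higher in replicate 1 and a median of 0.12. For TLR4 pathway genes the count depended on the scaling: 15 of 30 were higher, with a median of 0.01, against 13 (−0.03) in the rescaled TPM, 20 in CPM with no TMM factor and 27 (0.30) in the read-based TPM. Under TPM rescaled to protein-coding nuclear genes the interferon median was 0.62, with 28 of 30 members higher and the median of all genes at −0.12. In the read-based TPM it was 0.98, with all genes at 0.19. Ribosomal protein genes differed by −0.04, with 37 of 80 higher. Their sign turned with the scaling, from −0.31 (16 of 80 higher) in the rescaled TPM and −0.18 (25 higher) in TPM to 0.10 (55 higher) in the read-based TPM. In CPM with no TMM factor they differed by 0.11 (47 higher), where the median of all genes was 0.14.

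**Figure D3:**
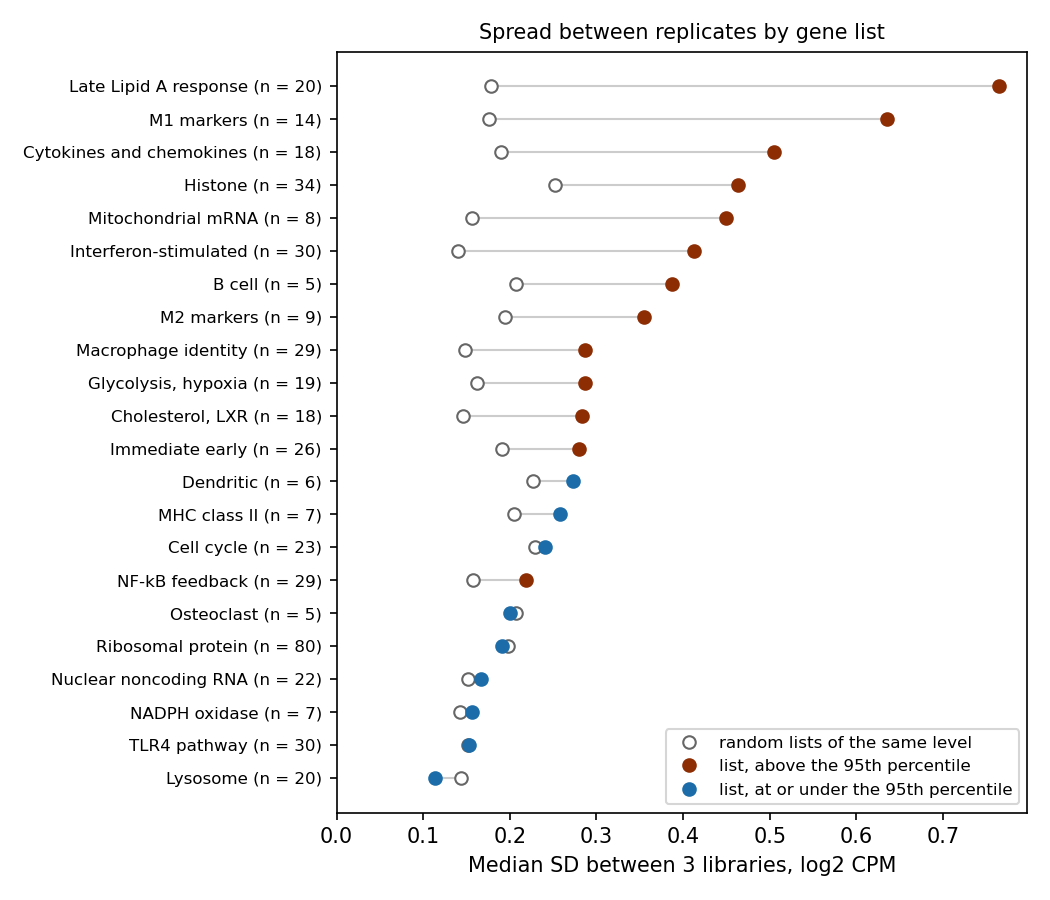
Median SD of log2 CPM between the 3 libraries for each list (filled) and for random lists of the same level (open), with the number of tested members in the labels. Late Lipid A genes lie farthest right at 0.76 and lysosomal genes farthest left at 0.11.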

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

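Sequences outside the gene annotation carried counts that none of the comparisons used. The entry for phiX, a bacteriophage genome used as a sequencing control, held 191325, 57501 and 51678 expected counts in replicates 1, 2 and 3. Summed over 26248 entries, tRNA genes held 50, 25 and 38 counts in the same order. The ERCC spike-in entries had 0 counts in all 3 libraries.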

How the results depend on the processing

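Of the alternatives in this section, fits on protein-coding nuclear genes only were chosen after seeing the data, and the others before. CPM with no TMM factor, used above for directions between replicates 1 and 3, was not among them. The means of the 6 list differences kept their sign under every alternative run, but sizes moved by more than 1 SD between libraries under several. A mean can hide a library of opposite sign: immediate early minus late was 0.48 ± 0.94 in the read-based tables. With a pseudocount of 1 they became 2.66 (NF-κB feedback minus cytokines), 5.29 (interferon minus cytokines), 2.34 (M1 minus M2) and 6.30 (macrophage minus other lineages). With members of mean TPM of 0.1 or more these were 1.87, 4.57, 2.73 and 6.54, and noncoding minus ribosomal protein was 1.73. In the read-based tables they were 2.79, 5.28, 2.24 and 8.31, with immediate early minus late at 0.48. In CPM without length scaling the differences were 3.41, 6.23, 2.62 and 6.51, with 0.43 for immediate early minus late and 2.36 for noncoding minus ribosomal protein. As means over members they were 2.79, 1.94 and 7.84 for feedback, M1 and macrophage, 0.35 for immediate early and 1.58 for noncoding. Low genes drive part of this by construction, since a pseudocount sets their value; the rest of the cause was not tested.

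Detected genes numbered 20888 in the read-based tables and 8476 at 5 TPM, against 13530. Genes variable between replicates numbered 271 in the read-based tables and 61 as DESeq2 dispersion outliers, against 167, and 57, 68 and 52 without replicates 1, 2 and 3, with fewer samples. The coefficient of variation ranged from 0.111 to 0.196 without 1 replicate, lowest without replicate 1. The share of the top 10 genes was 32.3% of expected counts and 28.5% of read-based TPM, and that of protein-coding genes 63.3% and 40.1%. The retained-intron share was 33.5% in the read-based tables. Of the remaining values, 77 moved by more than their spread and 125 did not, most of the former being list levels. With protein-coding nuclear genes only, 125 genes varied. Rescaling TPM to those genes raised log2 TPM by 1.74, 1.70 and 1.87 on the log2 scale in replicates 1, 2 and 3. No paired analysis was possible because there was 1 group. Depth limits Il6, Il12b and other genes with fewer than 10 counts.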

Other observations

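All tests of technical explanations address patterns that were first seen in these data, while the list levels were planned. Only for GC content and length was the expectation written before the result of the test. Gene groups not described above also differed in level. All 20 lysosomal genes were detected, with a median of 6.40 ± 0.05 on the log2(TPM + 0.1) scale (SD, n = 3). Psap, the precursor of saposins, stood at 763 ± 107 TPM and Grn at 373 ± 30.1. All 7 subunit genes of the NADPH oxidase, which makes superoxide in phagocytes, were detected at a median of 6.07 ± 0.24, with Ncf1 at 119.6 ± 20.4 and Cybb at 98.7 ± 25.1. Cholesterol and LXR genes had 18 of 20 members detected at 4.68 ± 0.41. The efflux pump genes Abca1 and Abcg1 stood at 102 ± 22.1 and 85.5 ± 14.4 TPM, while Ch25h, which encodes cholesterol 25-hydroxylase, was at 0.113 ± 0.0153. Glycolysis and hypoxia genes were detected for 18 of 20 members at 4.27 ± 0.17, led by Pkm at 105, 144 and 111 TPM in replicates 1, 2 and 3 and Pfkfb3 at 69.0 ± 15.0.

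MHC class II genes were lower, with medians between 2.27 and 2.62 and 7 of 10 detected. H2-DMa stood at 19.0 ± 3.13 TPM and the invariant chain gene Cd74 at 15.6 ± 1.51. Cell cycle genes had a median of 1.25 ± 0.12, or 2.48 in the read-based tables, with 17 of 26 detected. Among them Pcna was at 24.4 ± 6.23, and Cdc20 was the lowest of the list at 0.207 ± 0.150. Histone genes were at 1.25 ± 0.38, with 41 of 71 detected and Hist2h2aa2 highest at 40.4 ± 15.9. Osteoclast genes were at −1.78 ± 0.24 with 3 of 12 detected, led by Tnfrsf11a, the RANK receptor, at 38.5 ± 4.90. Progenitor genes were at −2.96 ± 0.20 with 2 of 14 detected, led by Ly6a at 21.5 ± 12.3. Neutrophil, NK, mast and epithelial lists all had a median of −3.32, the value of 0 TPM. The dendritic, fibroblast and endothelial lists were at −1.57 ± 0.13, −2.34 ± 0.87 and −2.63 ± 0.17. B cell, T cell and erythroid lists were at −2.76 ± 0.51, −2.98 ± 0.30 and −3.13 ± 0.34. All of these low cell type lists were higher in the read-based tables, with osteoclast genes at 0.37, dendritic at 0.23 and T cell at −0.83. Mast cell genes were led by Hdc at 1.83 ± 0.910 and fibroblast genes by Fap at 4.35 ± 1.20. The sex-linked list was at −3.23 ± 0.08 with 1 of 6 detected, or at 1.49 in the read-based tables. Xist, the RNA that coats the inactive X chromosome, reached 1071 ± 28.5 TPM. The Y-linked genes together had 0, 2 and 1 expected counts, and the labels do not record sex. For Uty, on the Y chromosome, the read-based tables gave a mean of 10.3 TPM against 0 in the gene tables.

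Interferon-stimulated genes were higher in replicate 1 than in replicate 3 by 0.80 on the log2 scale (bootstrap interval over members 0.59 to 0.84). Intervals in this and the next paragraph resample genes, so they do not measure the error between libraries. A wrong scale for a whole library would move genes of the same level alike. The list lay at the 100th percentile of random lists matched on level, whose median was 0.06. List and replicate pair were picked from these same values, so this restates the spread of the list and is no separate test. After removal of the trend on GC content and transcript length the difference was 0.71 (0.57 to 0.80), which argues against that bias as the whole cause. More mature cytoplasmic RNA in replicate 1 would raise ribosomal protein genes, which differed by −0.0428 (−0.19 to 0.05), while lysosomal genes, whose mRNAs are translated on membranes, differed by −0.13 (−0.21 to 0.07; 9 of 20 higher), or −0.19 to 0.19 across scalings. Mitochondrial mRNAs were higher by 0.89, which leaves RNA of attached mitochondria open, no biological explanation was tested, since there was 1 group, and RNA input cannot be told apart from replicate.

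U1 snRNA was higher in replicate 1 than the mean of replicates 2 and 3. CPM summed over 21 annotated copies were 1463, 184 and 272 in replicates 1, 2 and 3, and the difference of 2.71 on the log2 scale in the sum argues against reads moving between copies. The 14 tested copies held 5 different sets of counts, so their 14 calls are not independent. Effective lengths in the transcript tables imply fragments of 200, 255 and 245 nt, shortest in replicate 1, which may favour short RNAs. Other genes under 300 nt were higher in replicate 1 by 0.37 (0.03 to 0.63, 45 of 73 genes), less than the U1 difference. Among them, 9 other snRNA genes differed by 0.10 (−0.73 to 0.88). The short genes were pooled whatever their length, so a shift limited to RNAs as long as U1 is not excluded. The part played by fragment length therefore stays open, and no biological explanation was tested.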
